A study of Mus musculus with 10 samples.

How the data were processed

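RNA of c-Kit-positive cells from 5 mouse MLL-AF9 leukaemia lines was measured on 10 biotin-labelled 1-colour arrays, 1 per line and treatment. Per the labels' protocols, cells grew in RPMI with 20% serum, IL-3 and IL-6 at 10 ng/mL and SCF at 20 ng/mL, received 10 nM 4-OHT or ethanol, and gave total RNA by Trizol, of which 200 ng was labelled with the Ambion WT kit. Per the series design, the lines are independent primary leukaemias, cells of each were cultured with and without 4-OHT for 72 h, and c-Kit-positive cells were sorted by flow cytometry after Cre induction. Whether the vehicle and 4-OHT cultures of a line were handled on the same day is not given in the sources used here.

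The deposited table holds 1 intensity per probe set and array, which the authors made with RMA per the submitters' processing notes. RMA corrects the background, brings the probes of all arrays to one distribution and summarises them per probe set. Its software and version are not given in the sources used here. The deposited intensity values are on a linear scale, as their range shows, and log2 was taken of them here. Median signals were 144.7 to 158.2 and log2 interquartile ranges 2.67 to 3.05, the lowest on the vehicle array of line 10986. Arrays have no read depth, and signals near the array background have little precision, so the number of arrays and the level filter limit what can be seen.

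Of 35556 probe sets, 23410 are in the platform's probe annotation, 21789 of them with 1 gene symbol and 1621 with several, and 12146 are not listed there and are unnamed here. Of those with 1 symbol, 21698 had an Entrez identifier found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. No coordinates were used. A gene was represented by the probe set with exactly 1 symbol and the highest mean over all arrays, which gave 19938 genes. Genes with a mean log2 level at or above 6.23, the 25th percentile of all probe sets, were tested (15662 genes). Probe sets of 1 gene can disagree and only the brightest was used. All per-sample columns were used.

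Groups came from the labels: fl vehicle and fl 4-OHT (3 arrays each) and wt vehicle and wt 4-OHT (2 arrays each), with the cell line as replicate. Changes were tested with limma 3.58.1 in R 4.3.3 on all 10 arrays, with the cell line as a block and a separate 4-OHT term for fl and wt lines, moderated variances, two-sided tests and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The fit had 3 residual degrees of freedom and 6.694 in total with the prior of 3.694. The difference of the 4-OHT effect is the difference of the 2 terms. The fl and wt lines under vehicle were compared in a fit of 4 group means with the line as a random block (correlation 0.165, statmod 1.5.0). The block follows the series design, since each line was cultured both ways. As a check, the deviations of a line's vehicle and 4-OHT arrays from their group means correlated across genes at 0.78, 0.22 and -0.06 in lines 10949, 10950 and 10986 and at 0.43 in each of lines 10977 and 10980, so the arrays of line 10986 did not deviate together.

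Of 24 gene lists fixed by name, 21 were tested as sets. They cover the MLL fusion programme, stem and progenitor surface markers, monocyte and macrophage markers, primary granule and late granulocyte genes, and mast cell, erythroid and megakaryocyte, lymphoid and MHC class II markers. They also cover S phase, mitosis, p53 targets, the Bcl2 family, stress response, interferon, mitochondrial, cholesterol, glycolysis, MYC, immediate early and histone genes. The Zfx family, 2 genes recalled from the study's paper and the sex check genes were named but not tested as sets. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. For named genes, the rule was the passing genes with the same direction in every line pair, up to 12 each way in the fl lines and up to 5 each way in the other comparisons. Where fewer passed, the genes with the smallest unadjusted p filled up to 6 or 3, said not to pass. Zfx, Idh2, Ptpmt1 and Kit were always named, with up to 4 passing members of each list, or the 2 members with the largest change where fewer than 2 passed. These choices and the alternatives, apart from those named as later, were fixed before the data were examined. Thbs1, Cybb, Ccr2, Lyz2 in the fl comparison, the 4 smaller falls and the genes of the closing part were chosen after their values were seen.

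Most alternatives changed 1 choice. On block and filter they were no block, a random block, no level filter, a filter at the 50th percentile and all probe sets tested. On scale and variance they were arrays centred on their median, quantile normalization, and a trended and robust variance prior. The rest left out each line in turn, used only the arrays of a comparison, or used the other list tests. For single genes the prior was made trended and robust together, and the fit of only the vehicle arrays also had no block. A move in these fits cannot be put down to either choice alone. Chosen after seeing the data were array weights per line pair and fits without the vehicle array of line 10986. With the block, leaving out 1 array equals leaving out its line. The same steps were tested on simulated data for the fl comparison, in 5 sets of 15662 genes with 200 changed. They recovered 80% of genes with a log2 change of 1 and 99.2% of those with a change of 2, and 6.18% of the calls were false. The simulated noise was independent between genes and had the same spread on every array, with no line like 10986. These shares therefore describe the steps on such arrays and may not carry over to the real ones. The simulated variances were revised once, because the initial draw gave less spread than the arrays have. The deleted exons of Zfx were not given in the sources used here, and probe positions were not analysed here.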

Results

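Gene expression was measured on 10 microarrays of RNA from c-Kit-positive cells of mouse acute myeloid leukaemia driven by the MLL-AF9 fusion. The 5 lines were independent primary leukaemias that carried Cre-ER, a Cre recombinase switched on by tamoxifen. Lines 10949, 10950 and 10986 held a floxed allele of Zfx, an X-linked zinc finger transcription factor, and are called fl lines here. Lines 10977 and 10980 held the wild-type allele and are called wt lines. Each line was grown for 72 h with 10 nM 4-hydroxytamoxifen (4-OHT), which activates Cre, or with ethanol vehicle, and c-Kit-positive cells were sorted afterwards. This gave 3 fl vehicle, 3 fl 4-OHT, 2 wt vehicle and 2 wt 4-OHT arrays, 1 of each treatment per line. The question, from the series title, was how deletion of Zfx alters gene expression in these cells. The number of arrays limits the precision: the median standard error (SE) of a log2 change was 0.12 in the fl lines and 0.14 in the wt lines.

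The deposited signals had medians between 144.7 and 158.2 on the 10 arrays. The vehicle array of line 10986 stood apart from the rest. It lay at 49.4 on the principal component that held 47.2% of the variance, against -20.4 to 23.0 for the other 9 arrays. Its mean correlation across genes with the other arrays was 0.961, against 0.979 to 0.985 for the others. The log2 change of all genes in that line had an SD of 0.497, against 0.174 to 0.263 in the other 4 lines.

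**Figure D1:**
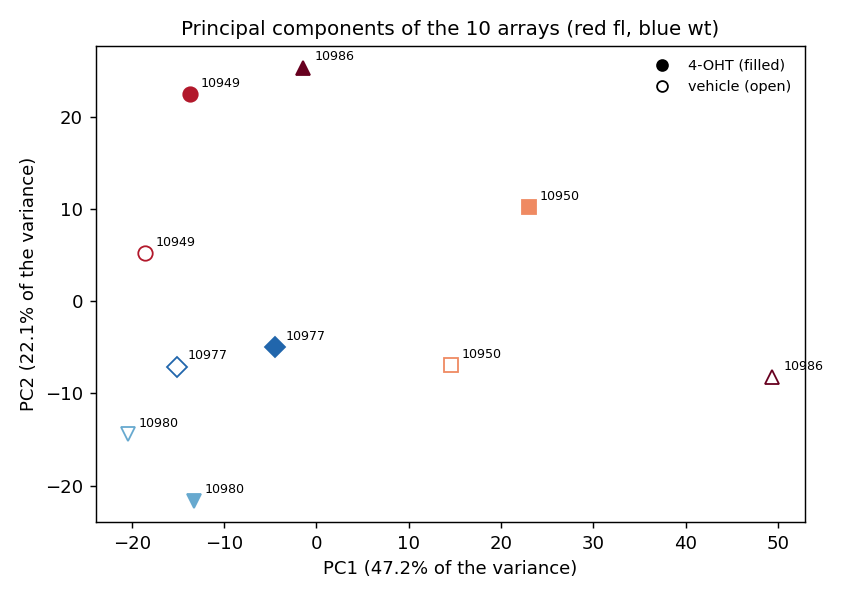
Each point is 1 of the 10 arrays on the leading pair of principal components (horizontal and vertical axes, component scores without unit), red for fl and blue for wt lines, open for vehicle and filled for 4-OHT. The vehicle array of line 10986 sits alone at 49.4 on the horizontal axis.

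The probe set of Zfx, the targeted gene, did not fall in the fl lines with 4-OHT. Its log2 level lay between 9.24 and 10.09 on the fl vehicle arrays and between 9.98 and 10.07 on the fl 4-OHT arrays, a change of 0.37 (SE 0.16, n = 3 line pairs, limma adjusted p = 0.407). The change was -0.02 in line 10949, 0.35 in line 10950 and 0.79 in line 10986, whose vehicle array had the lowest level. In the wt lines it was -0.12 (SE 0.19, n = 2 line pairs, adjusted p = 1), and the difference between the fl and wt lines was 0.50 (SE 0.25, adjusted p = 0.875). The deleted exons and the position of the probes are not given in the sources used here. A probe set outside the deleted part would not see the deletion, so these levels check neither the deletion nor the labels, and each fl 4-OHT array stands for cells in which deletion was induced per its label. Of the 4 genes of the Zfx family list, Zfx alone passed the level filter.

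With 4-OHT, 8 genes rose and 16 fell in the fl lines among 15662 genes tested. Mmp8, the neutrophil collagenase, rose most, by 2.56 on the log2 scale (SE 0.19, n = 3 line pairs, adjusted p = 0.0143). Vcan, a matrix proteoglycan made by monocytes, rose by 1.48 (SE 0.11, adjusted p = 0.0143), and Hpse, the heparan sulphate cleaving enzyme heparanase, by 1.63 (SE 0.17, adjusted p = 0.0373). Dab2, an endocytic adaptor, rose by 1.91 (SE 0.13, adjusted p = 0.0143) and Ctss, the lysosomal protease cathepsin S, by 1.40 (SE 0.16, adjusted p = 0.046). Dab2 has 1 other probe set with its symbol, whose values are not given here. Irf8, a transcription factor of monocyte and dendritic cell development, rose by 0.93 (SE 0.10, adjusted p = 0.0373). The integrin gene Itga1 and the small GTPase gene Rab19 rose by 1.42 (SE 0.14) and 1.11 (SE 0.13).

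The genes that fell belonged to varied processes. Npepl1, a putative aminopeptidase, fell most, by 1.88 (SE 0.11, n = 3 line pairs, adjusted p = 0.0143). Ankrd52, a regulatory subunit of a protein phosphatase, fell by 1.48 (SE 0.10, adjusted p = 0.0143), and Ext2, which elongates heparan sulphate, by 1.08 (SE 0.09, adjusted p = 0.0264). Among chromatin genes, Top2b, a DNA topoisomerase, fell by 1.20 (SE 0.12), the histone reader Zmynd11 by 1.26 (SE 0.12) and the histone variant H2ax by 1.40 (SE 0.16). H3c4 fell by 1.61 (SE 0.18), but histone genes have near-identical copies and its value is uncertain. Cibar1 fell by 1.61 (SE 0.13) to a mean of 5.77, below the level filter of 6.23, where array signals can understate a fall. Lrrc41 fell from a mean level of 8.53 to 7.03, the tyrosine phosphatase Ptpn9 by 1.17 (SE 0.11), the exoribonuclease Dis3l by 1.24 (SE 0.12) and the endosomal sorting gene Mvb12b by 1.24 (SE 0.14). Retsat, Fbxw5, Pyroxd2 and the myeloid transcription factor gene Cebpd, outside the 12 largest falls, also fell, with Fbxw5, Pyroxd2 and Cebpd at -0.87, -0.81 and -0.80 and Retsat at -1.10, -1.02 and -0.90 in the 3 lines.

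All 24 genes moved the same way in each of the 3 fl lines. The mean changes over both wt lines had a median of 0.01 for the 8 genes that rose (range -0.26 to 0.10) and 0.04 for the 16 that fell (range -0.18 to 0.23), but they average lines that moved apart. All 8 genes that rose in the fl lines moved up in wt line 10977, by 0.03 to 0.53, and 7 of the 8 moved down in line 10980, with changes from -0.55 to 0.03. The 16 that fell ran from -0.32 to 0.06 in line 10977 and from -0.07 to 0.47 in line 10980. At an unadjusted p under 0.05 there were 1931 genes (1046 higher, 885 lower), against 783 by chance, and the smallest adjusted p was 0.0143. Leaving out line 10949, 10950, 10977 or 10980 gave 0 calls, the fl arrays alone or all probe sets also gave 0, and leaving out line 10986 gave 144 genes that rose and 296 that fell. For this comparison the fits without line 10977, without line 10980 and with the fl arrays alone are the same. All 24 directions were kept in each of these fits, which is no check, since the genes moved the same way in every fl line. Without the line as a block 5 rose and 23 fell, 13 of the 24 genes among them, and those that fell short included Mmp8, Vcan, Hpse, Itga1, Ctss, Irf8, H3c4, H2ax, Zmynd11 and Top2b. The split was 31 against 34 with arrays centred on their median and 28 against 33 after quantile normalization.

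**Figure D2:**
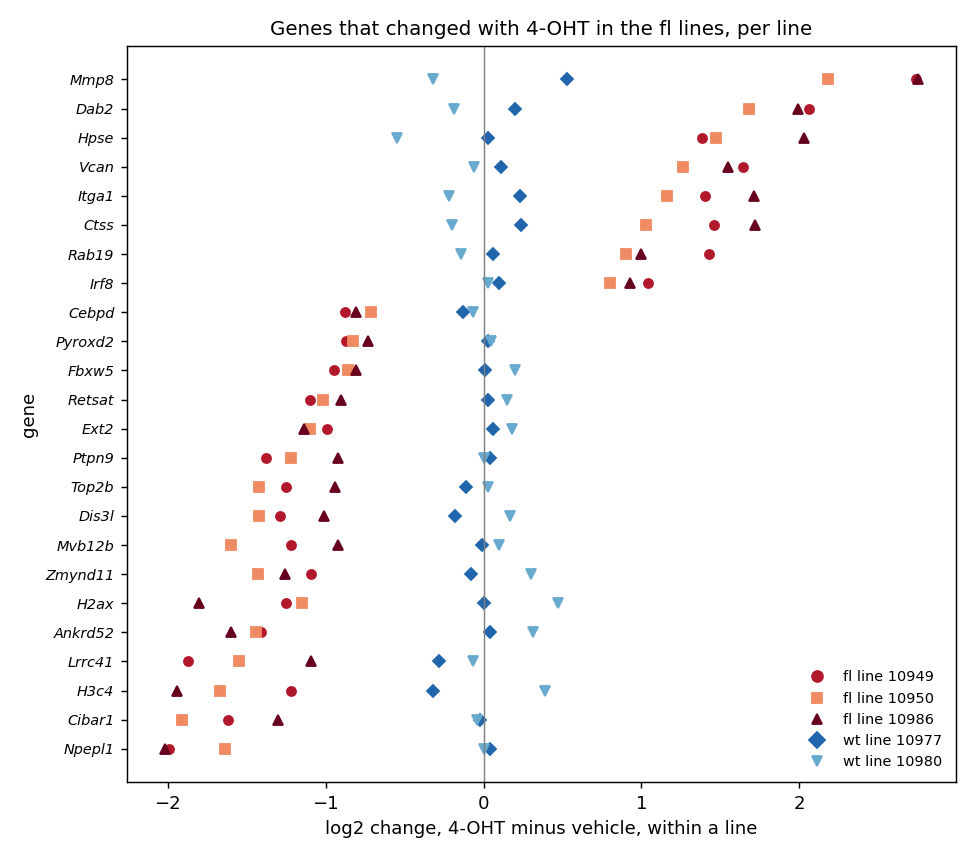
The 24 genes that changed in the fl lines (vertical axis) with the log2 change from vehicle to 4-OHT in each line (horizontal axis, 1 marker per line, red fl and blue wt). The medians in the fl lines were 1.45 for the 8 that rose and -1.24 for the 16 that fell.

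Idh2 and Ptpmt1, mitochondrial enzyme genes recalled from the study's paper, did not pass. Idh2 changed by -0.94 (SE 0.14, n = 3 line pairs, adjusted p = 0.0836), with -0.84, -0.81 and -1.17 in lines 10949, 10950 and 10986, and -0.06 and 0.52 in lines 10977 and 10980. Ptpmt1 changed by -0.97 (SE 0.19, adjusted p = 0.114), with -1.48, -0.98 and -0.44 in the fl lines. The study may have chosen both genes on these samples, so their direction is not independent evidence. Without line 10986, both passed, at -0.82 (adjusted p = 0.0251) and -1.23 (adjusted p = 0.00602), and over all alternatives their adjusted p ranged from 0.000323 to 0.336 and from 5.52e-05 to 0.373. Kit, the gene of the sorted surface receptor, changed by 0.20 (SE 0.12, adjusted p = 0.574).

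Of 21 gene lists, 7 passed limma's camera test in the fl lines with a preset correlation, and none of the 7 passed with an estimated correlation. Monocyte and macrophage markers rose as a set (mean log2 change 0.62, adjusted p = 3.72e-11, and adjusted p = 0.632 with an estimated correlation). Of 25 measured members, Vcan, Ctss and Irf8 rose and 22 did not pass, 13 rose adjusted over the list alone, and 17 moved up in all 3 fl lines. The lysozyme gene Lyz2 changed by 2.08 (SE 0.39, adjusted p = 0.111) and the NADPH oxidase gene Cybb by 1.32 (SE 0.28, adjusted p = 0.13), while Ccr2 changed by -0.16 (SE 0.23). The list mean was 0.61 in line 10949, 0.44 in line 10950 and 0.81 in line 10986, the line whose vehicle array stood apart, and 0.15 and -0.20 in wt lines 10977 and 10980. Late granulocyte genes also rose as a set (mean 0.37, median 0.17, adjusted p = 0.00689, and adjusted p = 0.902 with an estimated correlation). Of 19 members, Mmp8 rose and 18 did not pass, 4 rose and 1 fell adjusted over the list alone, and the chemokine receptor gene Cxcr2 changed by 1.08 (SE 0.21, adjusted p = 0.114).

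Histone genes fell as a set in the fl lines (mean -0.51, adjusted p = 4.52e-05, and adjusted p = 0.632 with an estimated correlation). None of 8 members passed over all genes, 4 fell adjusted over the list alone, and the linker histone genes H1f3 and H1f2 changed by -1.11 (SE 0.25) and -0.80 (SE 0.15). The mean was -0.44, -0.81 and -0.27 in lines 10949, 10950 and 10986, and also -0.28 in wt line 10977, against 0.07 in line 10980. Immediate early genes, which respond to growth and stress signals within minutes, fell as a set (mean -0.28, adjusted p = 0.00218, and adjusted p = 0.748 with an estimated correlation). None of 16 members passed over all genes, and 2 rose and 6 fell adjusted over the list alone. The AP-1 gene Jun changed by -1.30 (SE 0.31, adjusted p = 0.159) and the antiproliferative gene Btg2 by -0.97 (SE 0.19, adjusted p = 0.116). Jun had its highest level of the 10 arrays, 10.53, on the vehicle array of line 10986 that stood apart. Without that array and without the line as a block, an alternative chosen after seeing the data, neither the immediate early (mean -0.17) nor the late granulocyte list (mean 0.38) passed.

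The other 3 lists that passed in the fl lines moved less and none of their members passed over all genes. Mitosis genes had a mean of -0.11 (adjusted p = 0.0365, and 0.902 with an estimated correlation), with Kif23 and Mki67 both at -0.33 (SE 0.18 and 0.11) and 0 of 21 adjusted over the list alone. The mean was -0.18 and -0.32 in lines 10949 and 10950, 0.17 in line 10986, -0.23 in wt line 10977 and 0.12 in line 10980. Stem and progenitor surface markers had a mean of 0.34 (adjusted p = 0.0365, and 0.748 with an estimated correlation), 1 of 8 rose adjusted over the list alone, and Cd34 and Thy1 changed by 1.04 (SE 0.35) and 0.90 (SE 0.14). Cd34 changed by 2.09 in line 10986 and by 0.58 and 0.44 in the other fl lines. Interferon-stimulated genes had a mean of 0.14 (adjusted p = 0.0368, and 0.632 with an estimated correlation), with the chemokine gene Cxcl10 at 0.71 (SE 0.18), the RNA sensor gene Ddx58 at 0.43 (SE 0.13) and 0 of 19 adjusted over the list alone. Each of these 3 calls ended without line 10950 (means -0.01, 0.36 and 0.16), and the calls of the mitosis and interferon lists ended also without line 10949 (means -0.07 and 0.13). The call of the surface marker list ended also without line 10986 (mean 0.18), and without the line as a block it did not pass (adjusted p = 0.167, range over alternatives 0.00871 to 0.748). It passed under only 6 of 15 alternatives, both in the fl lines and for the difference between genotypes, and fell short in both also with the stricter level filter, quantile normalization, array weights, and without the block and the vehicle array of line 10986. The mitosis call ended also with a trended prior, and the interferon call with the stricter filter and without the block and that array.

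The remaining 14 lists did not pass in the fl lines. Their mean log2 changes were -0.08 for the MLL fusion programme, with Hoxa3 at -0.49 (SE 0.15) and Myc at -0.48 (SE 0.17), and -0.06 for primary granule and early granulocyte genes, with Cebpe at -0.51 (SE 0.10) and Cebpa at -0.48 (SE 0.14). Markers of other blood cells had means of 0.27 (mast cell, basophil and eosinophil, with Ccl3 at 1.52, SE 0.38, and Cpa3 at 0.89, SE 0.20), 0.03 (erythroid and megakaryocyte), 0.09 (lymphoid) and 0.06 (MHC class II and dendritic cell). S phase genes stood at 0.06 with E2f1 at -0.36 (SE 0.10) and Ccne1 at 0.35 (SE 0.09), p53 target genes at 0.16 with Trp53inp1 at 1.44 (SE 0.56), and the Bcl2 family at 0.07 with Bcl2l11 at 0.65 (SE 0.17). The integrated stress and unfolded protein response stood at -0.00, with Slc7a11 at 1.43 (SE 0.29) and Chac1 at -0.80 (SE 0.22), and 3 members rose and 3 fell adjusted over the list alone. Slc7a11 changed by 2.42 in line 10986, and without that line it passed at 0.93 (limma adjusted p = 0.0125). Metabolic lists had means of 0.07 (TCA cycle and mitochondrial genes), -0.08 (cholesterol synthesis) and -0.07 (glycolysis and hypoxia genes, with Vegfa at -1.18, SE 0.19), and MYC and ribosome biogenesis genes -0.00. Line 10986, whose vehicle array stood apart, weighed on several of these means. Without it those of the S phase and mitochondrial lists, 0.23 and 0.39 in that line, turned to -0.03 and -0.09, and the MLL fusion programme (-0.15) and cholesterol synthesis (-0.18) passed. Those of the lymphoid and MHC class II lists rested on the other fl lines and were 0.18 and 0.15 without it. In lines 10949, 10950 and 10986, p53 target genes stood at 0.12, 0.04 and 0.31 and the Bcl2 family at -0.05, 0.07 and 0.18. In the same order, primary granule genes stood at -0.17, -0.05 and 0.02 and the erythroid list at 0.12, 0.07 and -0.09. Adjusted over the list alone, 2 primary granule genes fell, 2 mast cell list genes rose, 2 mitochondrial genes fell, and 1 gene each of the p53 and glycolysis lists fell. Adjusted p ranged from 0.238 to 0.762 over these 14 lists, and the median had the other sign than the mean for the lymphoid, MHC class II, Bcl2 and glycolysis lists. Of the sex check genes, Eif2s3y and Uty changed by 0.46 (SE 0.25) and 0.45 (SE 0.24), with 1.29 and 1.23 in line 10986, whose vehicle array had their lowest levels.

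**Figure D3:**
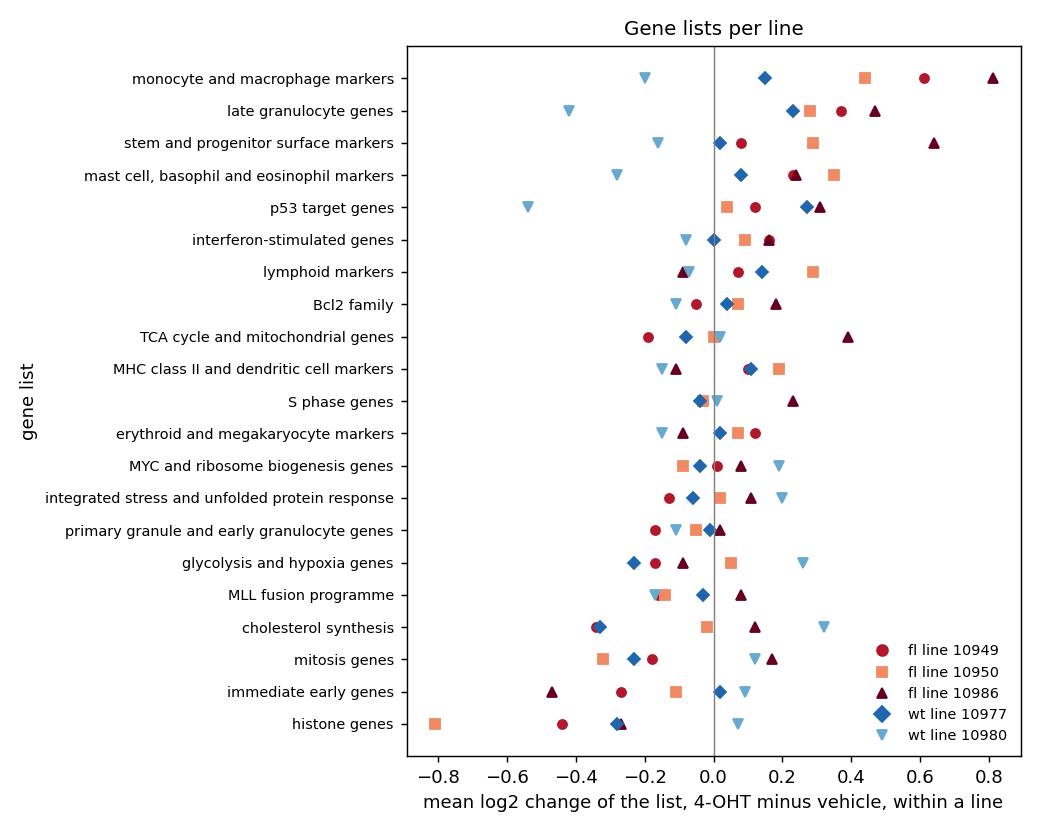
The 21 gene lists (vertical axis) with the mean log2 change of their members from vehicle to 4-OHT in each line (horizontal axis, 1 marker per line, red fl and blue wt). The monocyte and macrophage list lay between 0.44 and 0.81 in the fl lines, and p53 target genes lay at -0.54 in line 10980 and between 0.04 and 0.31 elsewhere.

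The wt lines give the effect of 4-OHT and Cre activity without a floxed allele, and no gene passed in them by limma. There were 0 genes past the threshold, 23 at an unadjusted p under 0.05 against 783 by chance, and the smallest adjusted p was 1. That is far fewer small p values than chance gives, so the lack of calls does not show that 4-OHT had no effect. The fit shares its spread with the fl lines. The changes of the wt lines correlated at -0.22 across genes, and opposite changes lower their mean and raise the SE. The changes with the smallest p that ran the same way in both wt lines were 0.32 for Fkbp5 (SE 0.12), 0.35 for Gml (SE 0.14) and 0.34 for Olfr172 (SE 0.12) upward. Downward they were -0.56 for Samd9l (SE 0.20), -0.49 for Gpr84 (SE 0.16) and -0.42 for Kcnip3 (SE 0.15), each with adjusted p = 1. Idh2 changed by 0.23 (SE 0.17), Ptpmt1 by -0.15 (SE 0.23) and Kit by 0.15 (SE 0.14).

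The wt lines moved apart from each other. In line 10980 the p53 target Trp53inp1 changed by -2.44, against 1.04 in wt line 10977 and 1.13 to 1.72 in the fl lines. Of the 50 genes with the largest change common to the 3 fl lines, a set formed after seeing the data, 40 (80%) moved the same way in line 10977 and 3 (6%) in line 10980. Thbs1, which encodes thrombospondin and was chosen after its values were seen, changed by 3.68 in line 10980 and by -4.07 in line 10977, with -1.89, -1.92 and -2.48 in the fl lines, and its fl change of -2.10 had an SE of 1.23 in the fit that shares 1 spread over both genotypes (adjusted p = 0.585). On its vehicle array line 10980 had Thbs1 at 7.66, within the range of the 4-OHT arrays of the other lines (7.47 to 8.91), and on its 4-OHT array at 11.34, within the range of their vehicle arrays (9.46 to 11.54).

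**Figure D4:**
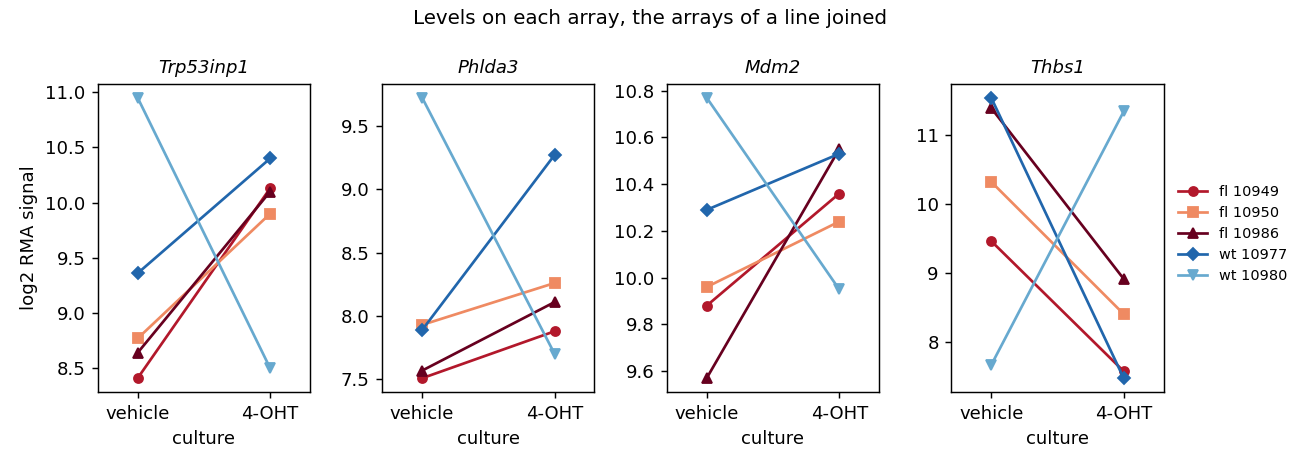
Log2 RMA signal (vertical axis) of 4 genes chosen after their values were seen, on the vehicle and 4-OHT array of each line (horizontal axis), the arrays of a line joined. Line 10980 runs against the other 4 lines, with Trp53inp1 at 10.95 under vehicle and 8.50 under 4-OHT.

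In the wt lines 2 of the 21 lists passed. The MLL fusion programme was lower (mean -0.10, adjusted p = 0.00849, and adjusted p = 0.893 with an estimated correlation), with Hoxa3 and Hoxa5 at -0.32 (SE 0.18) and -0.31 (SE 0.19). MYC and ribosome biogenesis genes were higher (mean 0.08, adjusted p = 0.00849, and adjusted p = 0.893 with an estimated correlation), with Mybbp1a and Rrs1 at 0.27 each (SE 0.13 and 0.16). Line 10980, which moved against the other lines, had means of -0.17 and 0.19 for these lists and line 10977 had -0.03 and -0.04. None of their members passed, adjusted over the list alone or over all genes. The other 19 lists had adjusted p from 0.097 to 0.956, and mean and median differed in sign for the surface marker and MHC class II lists. Without line 10980 neither call held (means -0.03 and -0.04, the MYC list turned) and 8 lists passed, without line 10977 13 lists passed, and without the line as a block 0 passed. The MLL call ended also with the stricter level filter and the MYC call with a trended prior.

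The difference of the 4-OHT effect between fl and wt lines tests directly what 4-OHT changed beyond its effect without a floxed allele, and limma called no single gene in it. The differences with the smallest p that parted all fl from all wt lines, 3 each way, belonged to genes that had changed in the fl lines. The difference was 1.90 for Dab2 (SE 0.20, n = 3 fl and 2 wt line pairs, adjusted p = 0.198), 2.45 for Mmp8 (SE 0.30, adjusted p = 0.284) and 1.46 for Vcan (SE 0.18, adjusted p = 0.284). It was -1.90 for Npepl1 (SE 0.17, adjusted p = 0.198), -1.66 for Ankrd52 (SE 0.16, adjusted p = 0.198) and -1.20 for Ext2 (SE 0.15, adjusted p = 0.284). For Idh2 it was -1.17 (SE 0.22, adjusted p = 0.594), for Ptpmt1 -0.81 (SE 0.30) and for Kit 0.05 (SE 0.18).

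For all 24 genes that changed in the fl lines, the 3 fl lines lay apart from the 2 wt lines with no overlap, and their unadjusted p for the difference was at most 0.00224. Both values are in large part set by how the genes were chosen, since the difference holds the same fl change. Chance gives no overlap in 20% of genes not chosen this way. Their adjusted p for the difference ran from 0.198 to 0.672, so that the test leaves open whether any of them differs. There were 0 genes past the threshold and 912 at an unadjusted p under 0.05, against 783 by chance. Without line 10986, whose vehicle array stood apart, 5 genes rose and 15 fell by this test, and without the line as a block 0 rose and 1 fell.

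Of the 21 lists, 5 passed for the difference, and none of them did with an estimated correlation. Monocyte and macrophage markers moved up further in the fl lines (difference of means 0.65, adjusted p = 1.39e-09, and adjusted p = 0.788 with an estimated correlation), and 7 of 25 passed adjusted over the list alone, with Lyz2 at 2.14 (SE 0.62). Under vehicle this list stood lower in the fl than in the wt lines, short of the threshold (mean -0.29, camera adjusted p = 0.107). From vehicle to 4-OHT, Lyz2 went from a mean of 9.79 to 11.87 in the fl lines, against 11.66 and 11.59 in the wt lines. Vcan went from 7.88 to 9.36, beyond its wt means of 7.72 and 7.74. Late granulocyte genes also moved up further (0.47, adjusted p = 0.00256, and adjusted p = 0.843 with an estimated correlation), and 1 of 19 passed adjusted over the list alone, with Mmp8 at 2.45 and Cxcr2 at 1.28 (SE 0.33). Stem and progenitor surface markers did so too (0.41, adjusted p = 0.0406, and adjusted p = 0.788 with an estimated correlation), with Thy1 at 0.88 (SE 0.23, adjusted p = 0.677) and an adjusted p of 0.902 for Cd34. Immediate early genes moved down further in the fl lines (-0.34, adjusted p = 0.00256, and adjusted p = 0.788 with an estimated correlation), with Jun at -1.76 (SE 0.49) and Btg2 at -1.12 (SE 0.30). Histone genes did so too (-0.40, adjusted p = 0.00809, and adjusted p = 0.788 with an estimated correlation), with H1f3 at -1.23 (SE 0.39) and H1f2 at -0.68 (SE 0.23). No member of the surface marker, immediate early or histone list passed adjusted over the list alone.

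Line 10980, which moved against the other lines, had a mean of -0.20 for the monocyte, -0.42 for the late granulocyte, -0.16 for the surface marker, 0.09 for the immediate early and 0.07 for the histone list. Line 10977 had 0.15, 0.23, 0.02, 0.02 and -0.28 for the same lists. The late granulocyte mean in the fl lines was 0.37, so that its call rests on line 10980. The other 16 lists had adjusted p from 0.0592 to 0.908, 1 gene of the mitochondrial list passed adjusted over the list alone, and mean, median or test differed in sign for the lymphoid and MHC class II lists. Without line 10980 the monocyte (0.47) and immediate early (-0.31) lists held and the late granulocyte (0.14), histone (-0.22) and surface marker (0.32) lists did not, so that 2 lists passed, against 14 without line 10977 and 10 without line 10986. Without line 10950 the histone (-0.25) and surface marker (0.43) lists did not pass and 3 lists did, and without the line as a block the surface marker list did not pass (adjusted p = 0.149, range over alternatives 0.00968 to 0.853) and the p53 target list did (0.29, adjusted p = 0.0496, range over alternatives 1.97e-07 to 0.855). Without the block and without the vehicle array of line 10986, an alternative chosen after seeing the data, the immediate early list did not pass either (-0.23).

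Under vehicle, where deletion was not induced, 3 genes were lower and 0 higher in the fl than in the wt lines. Trim12a, of the tripartite motif family, was lower by a log2 difference of -2.19 (SE 0.21, n = 3 fl and 2 wt lines, adjusted p = 0.0421). Its mean on the fl vehicle arrays, 5.64, lies below the level filter of 6.23, where array signals can understate a difference. Kcnip3, a calcium-binding protein gene, stood at -1.75 (SE 0.19) and Megf9 at -0.95 (SE 0.10), both with adjusted p = 0.0421. Dlk1, an imprinted gene of a membrane protein of the Notch ligand family, did not pass at 2.24 (SE 0.28, adjusted p = 0.081). Neither did the glutamine transporter gene Slc1a5 at 1.22 (SE 0.15, adjusted p = 0.081) or Rprl2 at 0.86 (SE 0.12, adjusted p = 0.124). By limma 1539 genes had an unadjusted p under 0.05 (581 higher, 958 lower), against 783 by chance. Leaving out line 10949, 10950, 10986 or 10980 gave 0 genes that were lower and leaving out line 10977 gave 15, and 2 were higher without line 10986. Only the vehicle arrays without a block, no level filter, the stricter filter, all probe sets or quantile normalization also gave 0 lower genes. Without the vehicle array of line 10986, 3 were lower and 3 higher.

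Under vehicle 9 lists differed between the fl and wt lines by the preset correlation, and none with an estimated one. The test with an estimated correlation used only the vehicle arrays without a block. The loss of these calls therefore cannot be put down to the correlation alone. Immediate early genes were higher in the fl lines (mean 0.58, adjusted p = 4.36e-07, and adjusted p = 0.554 with an estimated correlation), with 9 of 16 passing adjusted over the list alone, Jun at 1.91 (SE 0.41) and Zfp36 at 1.15 (SE 0.26). Histone genes were higher (0.62, adjusted p = 0.000925, and adjusted p = 0.554 with an estimated correlation), with 3 of 8 passing adjusted over the list alone, H1f2 at 1.23 (SE 0.27) and H1f3 at 1.19 (SE 0.37). Primary granule genes were lower (-0.52, adjusted p = 2.35e-05, and adjusted p = 0.554 with an estimated correlation), with 4 of 14 passing adjusted over the list alone, the myeloperoxidase gene Mpo at -1.18 (SE 0.31) and Prss57 at -1.11 (SE 0.67). Late granulocyte genes were lower (-0.56, adjusted p = 0.00444, and adjusted p = 0.554 with an estimated correlation), with 1 of 19 passing adjusted over the list alone, Ngp at -1.71 (SE 0.83) and Pglyrp1 at -1.51 (SE 0.57). The immediate early, histone and late granulocyte lists had the opposite direction in the fl lines with 4-OHT (-0.28, -0.51 and 0.37). So did the monocyte and macrophage list, which did not pass under vehicle (-0.29, against 0.62 with 4-OHT). Both comparisons use the same fl vehicle arrays, so a chance value on those arrays moves the results of a list in opposite directions.

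Of the other 5 lists that passed under vehicle, p53 target genes were lower in the fl lines (-0.34, adjusted p = 0.00455, and adjusted p = 0.6 with an estimated correlation), with Trp53inp1 at -1.55 (SE 0.60) and Phlda3 at -1.13 (SE 0.59). The vehicle array of line 10980, which moved against the other lines with 4-OHT, had Trp53inp1 at 10.95 and Phlda3 at 9.72, above the other vehicle arrays (8.41 to 9.36 and 7.51 to 7.93). S phase genes were lower (-0.18, adjusted p = 0.00455, and adjusted p = 0.6 with an estimated correlation), with Tyms at -0.42 (SE 0.26) and Ccne2 at -0.37 (SE 0.31). The integrated stress and unfolded protein response was lower too (-0.22, adjusted p = 0.0422, and adjusted p = 0.689 with an estimated correlation), with Slc7a11 at -0.89 (SE 0.54) and Asns at -0.76 (SE 0.36). Glycolysis and hypoxia genes were higher (0.19, adjusted p = 0.0308, and adjusted p = 0.689 with an estimated correlation), with Pfkl at 0.80 (SE 0.26) and Bnip3 at 0.68 (SE 0.40). Cholesterol synthesis genes were higher (0.19, adjusted p = 0.0353, and adjusted p = 0.689 with an estimated correlation), with 3 of 18 passing adjusted over the list alone, Insig1 at 1.02 (SE 0.25) and Mvd at 0.68 (SE 0.19). The other 12 lists had adjusted p from 0.0634 to 0.953, 1 surface marker and 2 erythroid list genes passed downward adjusted over the list alone, and mean, median or test differed in sign for the mast cell, erythroid, Bcl2, interferon and surface marker lists.

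Leaving out 1 line ended 5 of these 9 calls. The p53 call ended without line 10980 (mean -0.11), the late granulocyte call without line 10949 (-0.65), and the cholesterol call without line 10949 (0.09) or 10980 (0.04). The glycolysis call ended without line 10949 (0.17), 10986 (0.15) or 10980 (0.11), and the stress response call without line 10950 (-0.15), 10986 (-0.15) or 10977 (-0.22). The S phase (-0.09) and stress response (-0.16) calls ended after quantile normalization, and the stricter level filter ended both and the p53 call. The cholesterol call ended with no level filter.

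Across the 15662 genes, the 4-OHT effects in the fl and wt lines had a Pearson correlation of -0.29 and a Spearman correlation of -0.30. This is a correlation across genes, which are not independent replicates, and the effects share no array. Over the 6 combinations of 1 fl with 1 wt line it ran from -0.39 to 0.43, the fl lines correlated with each other at 0.07 to 0.55, and the wt lines with each other at -0.22. The correlation of the mean effects was 0.15 without line 10986, whose vehicle array stood apart, and 0.03 without line 10980, which moved against the other lines.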

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

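The tests on line 10980 and on the monocyte and macrophage list were chosen after the results they bear on were seen. In 5 gene lists the effect of 4-OHT differed between the fl and wt lines by the planned test of the difference with a preset correlation. The adjusted p was 1.39e-09 for monocyte and macrophage markers (difference 0.65), 0.00256 for late granulocyte genes (0.47), 0.00256 for immediate early genes (-0.34), 0.00809 for histone genes (-0.40) and 0.0406 for stem and progenitor surface markers (0.41). With an estimated correlation the adjusted p was 0.788 to 0.843. Without line 10980 the late granulocyte (0.14), histone (-0.22) and surface marker (0.32) lists did not pass, and without line 10950 neither the histone (-0.25) nor the surface marker list (0.43) did. The late granulocyte list rests on line 10980 (-0.42), since the fl mean of 0.37 stood against 0.23 in line 10977.

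Line 10980 moved against the other 4 lines, with p53 target genes at a mean of -0.54 against 0.04 to 0.31, Trp53inp1 at -2.44 against 1.04 to 1.72 and Thbs1 at 3.68 against -4.07 to -1.89. Of 50 genes chosen for moving one way in the other 4 lines, 2% moved that way in line 10980 (7% of 100 genes and 12% of 200). Genes chosen likewise moved the same way in 90% (line 10949), 92% (10950), 44% (10977) and 26% (10986) of cases. With 100 and 200 genes line 10986 stood at 20% and 17.5%, so it too ran against genes chosen on the other lines. Of 50 genes chosen on the 3 fl lines, 80% moved the same way in line 10977 and 6% in line 10980. An exchange of the vehicle and 4-OHT labels of line 10980 may account for its changes and stays open. On the 50 genes chosen on the other 4 lines its 4-OHT array scored -0.68, below the other vehicle arrays (-0.59 to -0.23). But its vehicle array scored 0.14, between these and the other 4-OHT arrays (0.27 to 0.79). A difference between its 2 cultures other than 4-OHT could also give the p53 value of -0.54, and neither 1 pair of arrays nor any label tells these apart, nor from a biological difference of this leukaemia, which was not tested. The labels were kept as given in every fit, so the wt comparison and the difference between genotypes rest on a pair whose direction is in doubt.

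Monocyte and macrophage markers rose in the fl lines by a mean of 0.62, with 17 of 25 members above the level filter up in all 3 lines and 1 down. Members up were 22, 21 and 20 in lines 10949, 10950 and 10986, and 20 and 9 in wt lines 10977 and 10980. These counts do not set line 10977 apart from the fl lines. Under vehicle the list mean was lower in the fl than in the wt lines (-0.29, not past the threshold), so a chance value on the fl vehicle arrays may enter the rise. Whether 4-OHT or Cre activity alone is the whole cause is not settled. The lowest fl line lay 0.23 above the largest size in a wt line, taken without its sign, against an SD of 0.19 over the fl lines. This is a narrow margin under a rule set after the values were seen. Chance alone also parts 3 lines from 2 with no overlap in 20% of cases. The tables argue against the vehicle array of line 10986 as the whole cause. Without that line the mean was 0.52 (camera adjusted p = 2.01e-08, range over alternatives 4.23e-13 to 0.632). Lines 10949 and 10950, at 0.61 and 0.44, lay above both wt lines. More mature cells passing the c-Kit gate, which should remove them, stay open. Kit did not fall (0.20, SE 0.12), but every array holds cells sorted on c-Kit, so its level cannot decide this. Cd68 (0.27), Fcgr3 (0.29) and Ccr2 (-0.16) moved less than Lyz2 (2.08) and Vcan (1.48), which would speak against such cells. But these 3 had the highest fl vehicle levels of the list (11.09 to 11.22), where a small share of mature cells would be hidden. A high level does not account for Cx3cr1 (-0.07, SE 0.15, level 8.26) or F13a1 (0.02, SE 0.36, level 7.66). Nor does it for Klf4 (-0.20), Itgax (-0.03) and Marco (0.05), which lay nearer the level filter. Against these, Ctss (1.40) and Clec7a (1.22) moved up from levels of 7.84 and 7.86, and 21 of 25 members had a positive change. The members were thus mixed and do not decide this. A rise of part of the monocyte genes with induced deletion of Zfx is a hypothesis that these values leave open, and the estimated correlation (adjusted p = 0.632) does not separate the list from other genes.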

How the results depend on the processing

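Array weights and the fits without the vehicle array of line 10986 were chosen after seeing the data, and the other alternatives were planned. In the fl lines all 24 genes kept their direction under every alternative (23 of 23 tested with the stricter filter). This adds little, since each of these genes moved the same way in all 3 fl lines. Still past the threshold were 13 without the block, 18 with a random block, 24 after centring, after quantile normalization and with array weights, 23 with a trended prior, 8 with no filter, 14 with the stricter filter, and 10 without the block and the vehicle array of line 10986. Genes that rose (8) and fell (16) became 5 and 23 without the block, 17 and 66 with a random block, 3 and 5 with no filter, 5 and 9 with the stricter filter, 31 and 34 after centring, 28 and 33 after quantile normalization. They became 0 and 0 with all probe sets tested, 16 and 18 with a trended prior, 0 and 0 with the fl arrays alone, 1698 and 2209 with array weights, and 5 and 22 without the block and the vehicle array of line 10986. Leaving out a line gave 0 to 144 and 0 to 296, the highest without line 10986 and 0 without any other. Every fit without a line leaves fewer residual degrees of freedom, that without line 10986 included, so this alone does not account for the 0 calls. More tests are adjusted for with no filter or all probe sets. Weights were 5.71, 0.66 and 0.16 for lines 10949, 10950 and 10986, so those counts rest mainly on line 10949.

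In the wt lines 0 genes passed by limma under the 15 alternatives run for them, the random block not among them (23 at an unadjusted p under 0.05 in the fit reported). For the difference (0 and 0, 912 at an unadjusted p under 0.05), 0 rose and 1 fell without the block, with or without the vehicle array of line 10986, 170 rose and 189 fell with array weights, and leaving out a line gave 0 to 5 and 0 to 15, the highest without line 10986. Under vehicle, the 3 lower genes became 0 with no filter, the stricter filter, quantile normalization, all probe sets or the vehicle arrays alone without a block, and 0 to 15 with a line left out, the 15 without line 10977. The 0 higher genes (581 at an unadjusted p under 0.05) became 3 without the vehicle array of line 10986 and 0 to 2 with a line left out, the 2 without line 10986.

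The 7 (fl), 2 (wt), 5 (difference) and 9 (vehicle) lists past the threshold became 0 in each comparison with an estimated correlation or with fry. Correlated genes alone do not account for this. The interferon list in the fl lines had an estimated correlation of -0.01, below the preset 0.01. Its camera adjusted p still went from 0.0368 to 0.632. Camera with an estimated correlation also works on the few residual degrees of freedom, and under vehicle both alternatives used only the vehicle arrays without a block. The list counts became 0 in the wt lines without the block and 1 there with a trended prior (camera has no robust form). They became 3 in the fl and 0 in the wt lines without the block and the vehicle array of line 10986. Leaving out a line gave 4 to 8 (lowest without line 10950), 2 to 13 (13 without line 10977, 8 without 10980), 2 to 14 (2 without line 10980, 3 without 10950, 10 without 10986, 14 without 10977) and 7 to 10. The MYC list in the wt lines turned to -0.04 without line 10980 and was 0.19 without line 10977, each a single wt line. The correlation of the effects, -0.29, was -0.44 to 0.15 with a line left out, the 0.15 without line 10986, and 0.03 without line 10980. The Zfx values stayed short of the threshold throughout (0.04 to 0.57 in the fl lines). Of the single genes' alternatives, 1430 stayed on their side of the threshold, 197 fell short, 69 newly passed and 0 reversed with a call in either fit. A sign change without a call in either fit counted as staying, as for Kit in the difference (0.05, range -0.04 to 0.20). Of the alternatives of lists that passed in the fit reported, which cannot newly pass, 230 kept direction and side, 96 fell short and 1 reversed. Without the block the surface marker list fell short in the fl lines and for the difference, and both wt lists fell short. The p53 list newly passed for the difference, with no other list call changed in these 3 comparisons. With the preset correlation the vehicle lists were not run without the block. Of the named genes, 10 fell short without it and Npepl1 newly passed for the difference, and centring and quantile normalization moved the median fl change by 0.008 and -0.005. Apart from the constructions named, the cause was not tested. The filter took the mean over all arrays, so genes low on every array were left out and their changes stay unseen, while 623 of the 15662 genes tested, Cibar1 and Trim12a among them, lay below it in at least 1 group.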

Other observations

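The gene choices below and the tests on the vehicle array of line 10986 were made after the results were seen, while the counts over other splits of the arrays were planned. Without line 10986, 20 genes passed the test of the difference between fl and wt lines, 16 of them among the 24 that changed in the fl lines. The other 4 were Chn2, a Rac GTPase-activating protein gene, at 1.34 (SE 0.14), Sccpdh at -1.13 (SE 0.13), Kdelr1, a receptor that returns proteins to the endoplasmic reticulum, at -1.20 (SE 0.15) and the Y RNA gene Rny1 at -1.75 (SE 0.18). In the line left out, Chn2 changed by 2.10 and Kdelr1 by -0.77, in the same direction, while Sccpdh (0.19) and Rny1 (0.21) did not follow. In all 5 lines 704 of 15662 genes moved one way, against 979 if directions were random and independent, so this alone singles out no gene. Among them Cd59a, which encodes a complement inhibitor, changed by -1.39, -1.27 and -0.22 in lines 10949, 10950 and 10986 and by -0.58 and -0.92 in lines 10977 and 10980. Cd59a lay at 6.28, 6.12 and 6.14 on the fl 4-OHT arrays and at 6.36 on the vehicle array of line 10986, close to the level filter of 6.23, where array signals can understate a change. The fatty acid receptor gene Gpr84 changed by -0.40, -0.74, -0.16, -0.54 and -0.45.

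Levels of Dlk1 and of its imprinted neighbour Meg3 did not overlap between the fl and wt arrays under either treatment, but neither gene passed the test. Dlk1 lay at 10.41 to 11.61 on the 6 fl arrays and at 8.22 to 8.97 on the 4 wt arrays, and Meg3, a non-coding RNA of the same region, at 7.99 to 11.17 against 7.55 to 7.64. Under vehicle the differences were 2.24 (SE 0.28, limma adjusted p = 0.081) and 1.23 (SE 0.77, adjusted p = 0.532), and Rian, of the same region, overlapped (6.37 to 9.13 on the fl arrays, mean difference 0.60, SE 0.63, adjusted p = 0.624). Trim12a, which did pass, had mean levels of 5.64 and 5.74 on the fl vehicle and 4-OHT arrays and of 7.83 and 7.60 on the wt arrays. With 3 lines against 2, chance alone parts the lines with no overlap in 20% of genes, these genes were chosen for it, and whether these are strain differences of the mice was not tested.

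The vehicle array of line 10986 stood apart from the other 9, with a mean correlation of 0.961 against 0.979 to 0.985 and an SD of the log2 change in that line of 0.497 against 0.174 to 0.263. A narrower range of values on that array is argued against as the whole cause, since after quantile normalization the SD was still 0.465, against at most 0.260 in the other lines. A lasting trait of line 10986 is argued against too, since the deviations of its 2 arrays from their group means correlated at -0.06. RNA quality, the state of that culture or the sorted cells may have differed, and none of these was tested. Of 10 splits of the 6 fl arrays, 3 gave as many genes as the real one, the real split included. The real split gave 24 and the highest other 2122, from a pair of splits that part only the arrays of line 10986. With the line block such a pair is 1 test made in both directions, on the 4-OHT change of that line alone, so it is no random grouping. For lists 1 of 10 gave as many, the real split itself, with 7 there and 6 in the highest other. Because such pairs repeat a test, the distinct tests are fewer than 10. The smallest possible share is then above 0.1, and the splits are too few to exclude chance. Among the 4 splits that part all 3 pairs, the highest other gave 0 genes and 2 lists.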
